A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

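PolyA RNA was measured by sequencing in 22 libraries of the budding yeast strain W303. Cells grew in a rich medium with 2% raffinose and received 2% galactose for 4 h, per the labels. They carried a multicopy plasmid that was empty (5 libraries) or held PSD1 (6 libraries) or V5-tagged PSD1 (5 libraries) behind the galactose-inducible GAL1-10 promoter. A further 6 libraries came from cells that carried the PSD1 plasmid and lacked PDR3. The labels name RNeasy columns and NeoPrep library preparation. They do not say whether the replicates were separate cultures, so the p-values measure the spread between samples, some of which may be technical repeats.

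The deposited count table held expected counts per gene, a unit that RSEM gives, and the values were whole numbers, so they are taken as rounded estimates. The submitters' processing notes name STAR 2.5.3a, RSEM 1.3.0, SAMtools 1.3 and the sacCer3 genome, without a role or an order for each. The deposited normalised table held log2 values, and the numbers behind them had 2 decimals once a pseudocount of 1 was removed, which is log2 of FPKM plus 1, per the file headers and the values. The annotation used for counting, its strand setting and any filter are not given in the sources used here. Without a strand setting, overlapping and antisense genes cannot be told apart and their values are uncertain. Genes with near-identical copies, such as Ty elements, hexose transporters, ENA pumps, Hsp70 pairs and duplicated ribosomal protein genes, share reads, so their values are uncertain too.

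Each column was joined to its sample by the library number in the label. In 2 count columns the replicate number differed from the label, and the library number decided. The count table had 7126 entries, of which 6048 matched a locus of the R64 reference annotation (the sacCer3 sequence) and 1078 did not. The unmatched entries held 1.68% to 3.05% of the counts of a library. Coordinates come from that annotation. In 1594 cells the count was 0 while the FPKM was above 0, so the count table does not hold every read fraction behind the FPKM.

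Total counts per library ran from 8.15 to 20.8, with a median of 13.5, in units of 10 to the power of 6. Intervals and floors given for low counts cover counting error only, at the 95% level for the interval and 3 counts for the floor. Libraries fell into a series numbered 5 (12 libraries) and a series numbered 6 (10 libraries) by the first digit of the library number, and every group had libraries in both.

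Genes with enough counts for testing were kept with edgeR's filterByExpr by group, which left 6278 genes. Normalisation used the trimmed mean of M values (TMM). edgeR 4.0.16 fitted 1 quasi-likelihood model to all 22 libraries with the 4 groups and the library series as terms. Each comparison was a contrast in that model, and p-values were adjusted by the Benjamini-Hochberg method over all genes at a threshold of 0.05. Levels are given as counts per 10 to the power of 6 (CPM, with TMM library sizes) with the SD over libraries, and differences as log2 fold changes with their standard error (SE). All adjusted p-values of single genes below come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. The other software was R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

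The comparisons, the tests, 27 gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. The rule named PSD1, PDR3, CIS1, MSP1 and PDR1 in each comparison. It then took up to 10 genes with the largest rise and 10 with the largest fall that passed and had a mean of at least 5 CPM over both groups. Their group means of log2 CPM also had to differ in the same direction in both library series. From each list it took up to 4 members with the largest change that passed, or 2 where none passed.

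The lists covered the pleiotropic drug resistance (PDR) regulon, galactose genes, phospholipid synthesis, the iron regulon, mitochondrial chaperones and proteases, mitochondrial protein import, cytosolic heat shock (Hsf1), the proteasome, the unfolded protein response, oxidative phosphorylation, the TCA cycle and the retrograde response. They also covered cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, general stress (Msn2/Msn4), oxidative stress (Yap1), amino acid synthesis (Gcn4), ergosterol synthesis, the phosphate regulon, glucose-repressed carbon use, glycolysis, histones, both mating types, and meiosis and sporulation. The list of mitochondrially encoded genes had fewer than 3 measured members in polyA RNA and was not tested, which left 26 lists. Lists were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, then with an estimated correlation, with adjustment over 130 tests of a list in a comparison. Camera compares a list with all other genes. Limma's fry was also run: its directional p asks whether the genes of a list move, on balance, one way, its mixed p whether they change in either direction, and neither compares the list with other genes.

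The steps were tested on simulated counts drawn from the real means, dispersions and library sizes, with changes of 1.5, 2 and 4 fold in known genes. For PSD1 against the empty vector (6262 genes), 76.1%, 88.1% and 100% of the changed genes were recovered at these folds. For the PDR3 deletion against PSD1 (6261 genes) the shares were 71.6%, 94.0% and 98.5%. For V5-PSD1 against the empty vector (6254 genes) they were 70.1%, 82.1% and 97.0%, and for PSD1 against V5-PSD1 (6259 genes) 73.1%, 89.6% and 95.5%. For the deletion against the empty vector (6256 genes) they were 68.7%, 85.1% and 98.5%. Among the unchanged genes of these 5 simulations 9, 15, 7, 5 and 12 passed, in the same order.

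Alternatives replaced TMM by DESeq2's size factors, edgeR by DESeq2, the filter by none, and the library series by no term, by the replicate number or by blocks of neighbouring library numbers. The number of PSD1 replicate 6 is no neighbour of its block. Others used each library series alone, the 2 compared groups alone, limma on the deposited log2 FPKM values, library sizes without PSD1, and each library left out in turn. After the data were seen, an alternative without the third replicates of both PSD1 groups and another with the loci of the reference annotation alone were added. Other splits of the libraries into groups of the same sizes were drawn, up to 100 per comparison with the real one. Comparisons that share libraries were set beside simulated unchanged groups, beside the overlap of independent lists, and beside values from split controls. The simulated groups drew each gene independently of the others. No library was left out of the comparisons.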

Results

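Cells that carried the PSD1 plasmid raised genes of drug resistance, protein folding and the proteasome, and lowered genes of cytosolic ribosomes and respiration. Deletion of PDR3 lowered CIS1, PDR5, PDR15 and other drug resistance genes, and no heat shock, proteasome or ribosome gene passed in that comparison. Cells with the V5-tagged plasmid, whose PSD1 mRNA was at least as abundant, raised heat shock genes and showed no call among drug resistance genes. PSD1 (YNL169C, sacCer3 chromosome XIV, 316169 to 317671) encodes the mitochondrial phosphatidylserine decarboxylase. Its mRNA was at 431 ± 143 CPM with the empty vector (n = 5), 15252 ± 6041 CPM with the PSD1 plasmid (n = 6), 18144 ± 4805 CPM with that plasmid in the PDR3 deletion (n = 6) and 24678 ± 4199 CPM with the V5-PSD1 plasmid (n = 5).

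**Figure D1:**
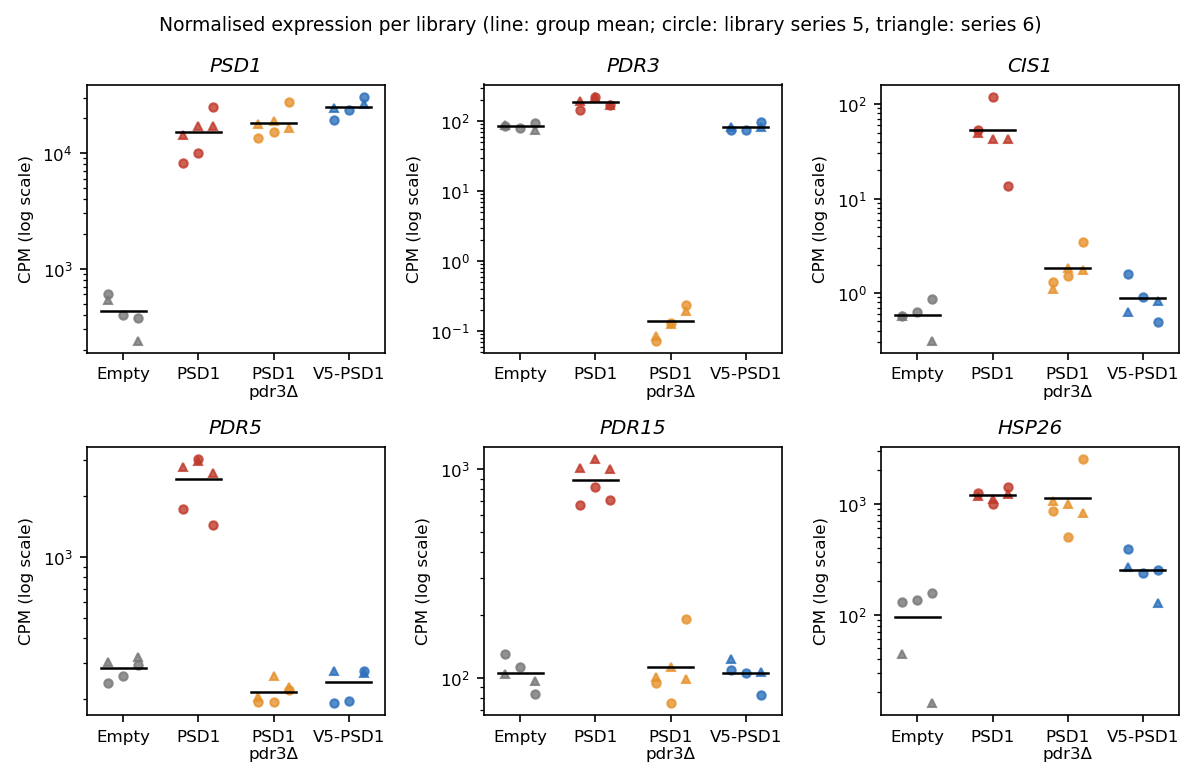
Level of 6 genes in each of the 22 libraries, in CPM on a log axis; lines are group means, circles library series 5 and triangles series 6. CIS1, PDR5 and PDR15 were high with the PSD1 plasmid and low in the other 3 groups, while HSP26 stayed high in the PDR3 deletion.

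**Figure D2:**
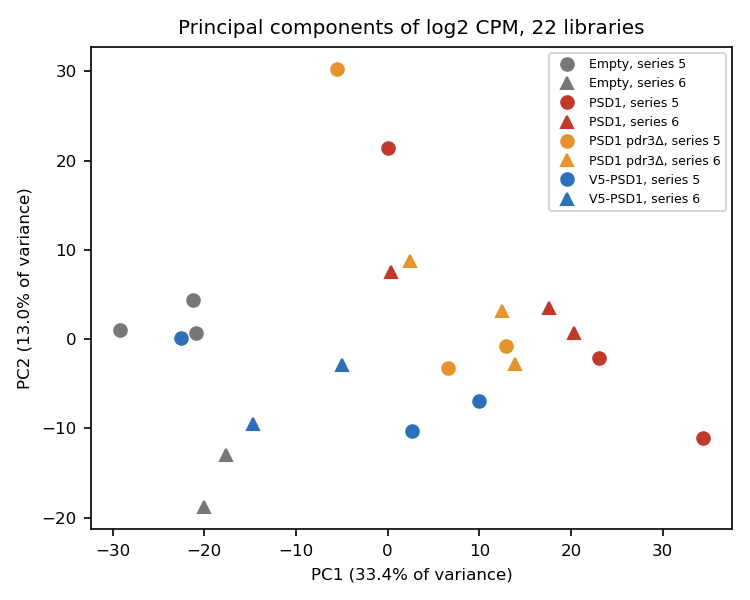
First principal component (33.4% of the variance) against the second (13.0%) of log2 CPM of the 1000 most variable genes, 1 point per library. The 5 empty-vector libraries lie at the left with the third V5-PSD1 replicate among them, and the third replicates of both PSD1-plasmid strains lie apart at the top.

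With the PSD1 plasmid, CIS1 (YLR346C, chromosome XII, 822287 to 822592) rose 93.3 fold over the empty vector, from 0.590 ± 0.199 to 53.5 ± 35.3 CPM (log2 fold change 6.54 ± 0.49 SE, adjusted p = 4.06e-09). CIS1 is known as a factor of the mitochondrial import stress response, which acts with the outer-membrane ATPase Msp1. PDR5 (YOR153W, chromosome XV, 619840 to 624375), which encodes a drug efflux pump of the ABC family, rose from 285 ± 33.2 to 2435 ± 683 CPM (3.06 ± 0.16, adjusted p = 1.02e-10). Its relative PDR15 (YDR406W, chromosome IV, 1279210 to 1283799) rose from 105 ± 17.3 to 890 ± 181 CPM (3.06 ± 0.21, adjusted p = 1.9e-09). YGR035C rose by 3.78 ± 0.54, or 3.04 without PSD1 replicate 2. PDR3 (YBL005W, chromosome II, 217470 to 220400), which encodes a transcription factor of these genes, rose 2.21 fold (1.14 ± 0.11, adjusted p = 5.95e-08). CIS1, PDR5, PDR15 and PDR3 were higher in 6 of 6 PSD1 libraries than in every empty-vector library. MSP1 (YGR028W, chromosome VII, 542203 to 543291) rose by 0.33 ± 0.07 (adjusted p = 0.000259), and PDR1, at 0.12 ± 0.07, did not pass (adjusted p = 0.17). Of the 19 measured genes of the PDR regulon, 15 rose, none fell and 4 did not pass. Adjusted over the list alone, 16 rose. The list stood above all other genes in camera (adjusted p = 7.42e-07), and this call was lost with adjusted p = 0.342 with an estimated correlation.

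In all, 1863 genes rose and 1689 fell with the PSD1 plasmid, of which 291 and 42 by at least 2 fold. The 42 became 80 without PSD1 replicate 3, 73 without PSD1 replicate 5, 70 and 73 with the replicate number and the library set as a block, 65 with limma on FPKM and 20 with the loci of the reference annotation alone. The median over all genes was 0.0186, which TMM sets near 0, so the changes are relative to other genes. Of the genes that passed, 1821 rose and 1821 fell with DESeq2, and 1691 and 1847 with limma on FPKM. With PSD1 left out of library sizes 1758 rose and 1821 fell. Which direction held more genes thus depends on the normalisation. Heat shock genes were among the largest rises. HSP26 (YBR072W, chromosome II, 382030 to 382674), a small heat shock protein, went from 96.5 ± 62.0 to 1199 ± 141 CPM (3.90 ± 0.46, adjusted p = 8.28e-07). The Hsp70 gene SSA3 (YBL075C) rose by 3.65 ± 0.35 and HSP33 by 3.24 ± 0.25. Of 25 genes of the cytosolic heat shock (Hsf1) list, 24 rose and none fell, in both adjustments, with SSA4 at 2.36 ± 0.26 (camera adjusted p = 1.55e-14; adjusted p = 0.23 with an estimated correlation). Of 33 proteasome genes 32 rose, among them PRE3 (0.84 ± 0.08) and RPN4 (0.83 ± 0.11), the transcription factor of proteasome genes (camera adjusted p = 7.86e-13; adjusted p = 0.392 with an estimated correlation). General stress genes (Msn2/Msn4) rose in 28 of 30 cases, as TMA10 (2.46 ± 0.13) and HSP12 (2.32 ± 0.27) did (camera adjusted p = 1.38e-10; adjusted p = 0.407 with an estimated correlation). In the oxidative stress (Yap1) list 16 of 22 rose and 1 fell (17 and 1 over the list alone). GRE2 (2.76 ± 0.22) and the peroxiredoxin gene AHP1 (2.32 ± 0.17) led it (camera adjusted p = 1.96e-05; adjusted p = 0.392 with an estimated correlation).

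Genes of mitochondrial protein folding and import rose too. The chaperonin genes HSP10 (1.59 ± 0.12, from 181 ± 24.6 to 543 ± 88.0 CPM) and HSP60 (1.38 ± 0.11) and the disaggregase gene HSP78 (1.40 ± 0.12) were among 12 of 19 mitochondrial chaperones and proteases that rose, with none lower. Camera gave adjusted p = 6.06e-05, and adjusted p = 0.252 with an estimated correlation. Of 35 import genes 23 rose and 2 fell, with MIA40 at 1.03 ± 0.11 and TIM13 at 0.78 ± 0.09 (camera adjusted p = 0.00108; adjusted p = 0.532 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes 65 rose, such as RSM19 (0.95 ± 0.13) and MRPL28 (0.89 ± 0.09), in camera with adjusted p = 9.97e-17 (adjusted p = 0.451 with an estimated correlation). Respiration went the other way: 30 of 36 oxidative phosphorylation genes fell and none rose, among them ATP2 (−0.68 ± 0.13) and CYT1 (−0.65 ± 0.11), with camera adjusted p = 2.21e-09 (adjusted p = 0.444 with an estimated correlation). In the TCA cycle 7 of 15 fell, as FUM1 did (−0.65 ± 0.16), and 2 rose (camera adjusted p = 0.152). In the retrograde response 3 of 10 fell, among them DLD3 (−0.59 ± 0.17; camera adjusted p = 0.223).

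Cytosolic ribosome genes made up the largest group that fell. Of 138 ribosomal protein genes 127 fell and 1 rose (130 and 1 over the list alone), as RPS20 did (−0.85 ± 0.09, from 834 ± 78.5 to 461 ± 42.9 CPM). Camera gave adjusted p = 7.00e-22, and adjusted p = 0.453 with an estimated correlation. Of 46 ribosome biogenesis genes 43 fell (44 over the list alone), with the RNA polymerase I genes RPA135 (−0.98 ± 0.12) and RPA190 (−0.96 ± 0.15) and with UTP22 (−0.95 ± 0.11). The camera adjusted p was 1.28e-15, or adjusted p = 0.392 with an estimated correlation. Amino acid synthesis genes (Gcn4) fell in 27 of 39 cases and rose in 7, with ARG3 going from 289 ± 11.2 to 144 ± 21.9 CPM and LEU9 at −0.88 ± 0.10 (camera adjusted p = 3.20e-05; adjusted p = 0.444 with an estimated correlation). Glycolysis genes rose in 10 of 16 cases, among them ENO1 (1.36 ± 0.25) and PGK1 (1.05 ± 0.12), with camera adjusted p = 0.00164 (adjusted p = 0.453 with an estimated correlation). Ergosterol synthesis had 13 of 24 higher and 2 lower, led by ERG28 (0.96 ± 0.07; camera adjusted p = 0.0483; adjusted p = 0.532 with an estimated correlation; adjusted p = 0.0636 with DESeq2 values). This camera call was lost in 11 of 14 alternatives and in 8 of 22 runs without 1 library (replicates 1 and 4 of the empty vector, 3 and 6 of PSD1, 2 and 4 of the deletion, 1 and 3 of V5-PSD1; highest adjusted p = 0.0904). Galactose genes fell in 7 of 11 cases, with GAL1 at −0.72 ± 0.10, and PGM2 (0.78 ± 0.18) was 1 of 2 that rose (camera adjusted p = 0.0368; adjusted p = 0.532 with an estimated correlation). This camera call was lost without PSD1 replicate 1 (adjusted p = 0.0552), 3 (adjusted p = 0.0511) or 5 (adjusted p = 0.0561).

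In the other lists camera passed for none. Phospholipid synthesis had 6 of 16 lower, such as INO2 (−0.66 ± 0.19), and 1 higher (5 and 1 over the list alone; adjusted p = 0.219). In the iron regulon 5 of 21 rose and 1 fell, with FET3 at −0.75 ± 0.30 and FIT3 at 0.65 ± 0.26 (2 rose and none fell over the list alone; adjusted p = 0.448). FET3 lost its call without replicate 1, 3, 4 or 5 of the empty vector or 1, 2, 4 or 6 of PSD1 (highest adjusted p = 0.0842). FIT3 lost it without any 1 of the empty-vector libraries, PSD1 replicate 2 or 4, or deletion replicate 4 (highest adjusted p = 0.102). The unfolded protein response had 2 of 17 higher, ERV2 (0.66 ± 0.09) and YET3 (0.64 ± 0.10), and 5 lower (4 over the list alone), such as LHS1 (−0.57 ± 0.16; adjusted p = 0.653). Of 20 glucose-repressed carbon use genes 6 rose, as SUC2 did (1.22 ± 0.18), and 5 over the list alone (adjusted p = 0.205). The phosphate regulon had 1 of 15 higher, PHM8 (0.91 ± 0.14), and 3 lower (1 and 1 over the list alone; adjusted p = 0.515). HTB2 (−0.37 ± 0.14) was the 1 of 8 histone genes that fell, and none passed over the list alone (adjusted p = 0.557). HTB2 lost its call without replicate 1 or 5 of the empty vector or 2 or 3 of PSD1 (highest adjusted p = 0.0861). In mating type a, 3 of 7 rose and 2 fell (3 and 3 over the list alone), with MFA1 at 0.71 ± 0.22 and STE6 at −0.61 ± 0.13, and the median (−0.31) and the mean (0.05) of the list differed in sign (adjusted p = 0.882). In mating type alpha 1 of 4 rose (none over the list alone; adjusted p = 0.372), and in meiosis and sporulation 6 of 12 rose and 1, SPS4 (−0.96 ± 0.14), fell (adjusted p = 0.152).

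Several of the largest changes lay in Ty elements or in loci that the reference annotation lacks. YPR137C-B (chromosome XVI, 805001 to 810269) had 0.0628 ± 0.14 CPM with the empty vector and 13.4 ± 11.2 CPM with PSD1 (7.34 ± 2.03, adjusted p = 0.00443). It had counts in 4 of 6 PSD1 libraries, none in replicates 3 and 5, and in 1 of 5 empty-vector libraries, replicate 5 with 5 counts. Without that library it was at least 221 fold higher against a floor of 3 counts over the group. This leaves out the only empty-vector library with counts, so it is no bound for the whole group. YNL054W-A rose by 3.30 ± 1.23, or 4.04 without replicate 4 of the empty vector, and lost its call without replicate 1, 2 or 3 of the empty vector or 1 of PSD1 (highest adjusted p = 0.0658). YLR410W-A had a count of 0 in all 6 PSD1 libraries and 0 to 2083 counts in the 5 empty-vector libraries. With PSD1 it was at least 974 fold lower against a floor of 3 counts over the group. Without replicate 3 of the empty vector, which held the 2083 counts, it was at least 268 fold lower. The deletion group, which carried the same plasmid, did hold counts at YLR410W-A. YBL005W-A, next to PDR3 on chromosome II (221330 to 222652), had 21 to 34 counts in the empty-vector libraries, 0 in all PSD1 and deletion libraries and 0 to 71 with V5-PSD1, so it was at least 49.9 fold lower in PSD1 and 52.7 fold lower in the deletion against the same floor. YDR210C-D fell by 1.29. Loci absent from the annotation were YLR286W-A (4.30 ± 1.39) and YDR406W-A (3.30 ± 0.45), which rose, and YNL174W (−2.16), YLL044W (−2.13), YML090W (−1.98), YBR113W (−1.38), YGR190C (−1.27), YBL039C-A (−1.22) and YBL100C (−1.17), which fell. YNL174W lost its call in 5 of 12 alternatives and in 15 of 22 runs without 1 library (highest adjusted p = 0.0907), and was at −2.90 without PSD1 replicate 3, as YLL044W was at −3.07. YLR286W-A was at 5.08 without replicate 5 of the empty vector and 3.69 without PSD1 replicate 6. OPT2, which encodes an oligopeptide transporter, fell from 227 ± 24.7 to 89.8 ± 33.2 CPM (−1.34 ± 0.18, adjusted p = 3.43e-06), in 6 of 6 libraries below every empty-vector library.

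**Figure D3:**
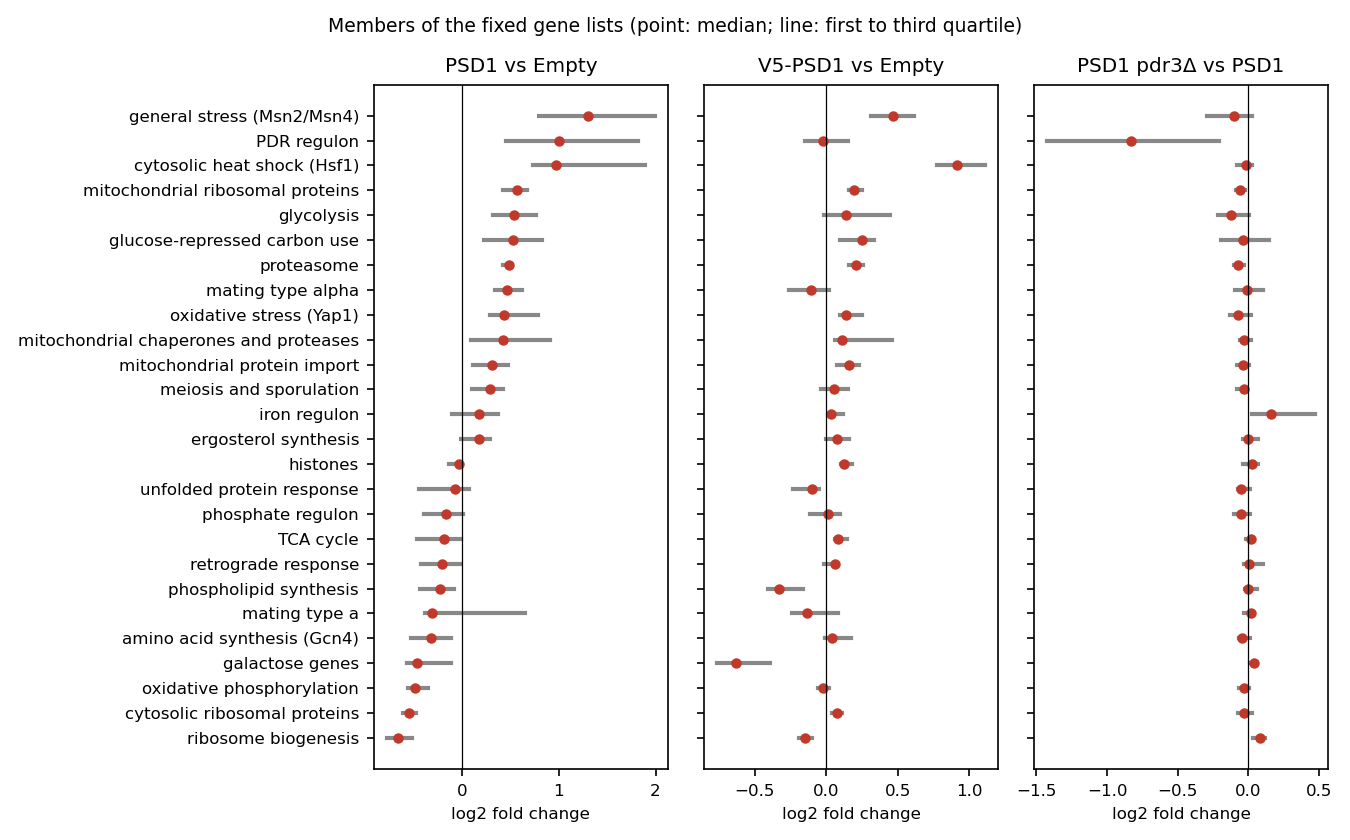
Median log2 fold change of the members of 26 gene lists (points) with quartiles (bars) in PSD1 against the empty vector, V5-PSD1 against the empty vector, and the PDR3 deletion against PSD1. The PDR regulon is high in the first comparison and low in the deletion.

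Deletion of PDR3 in cells with the PSD1 plasmid left 1 gene higher and 25 lower than in PDR3 cells with the same plasmid. The 2 groups alone gave 0 and 12, the replicate number as a block 1 and 22, and the library set as a block 4 and 29. Of the 6278 tested genes 331 had unadjusted p below 0.05, near the share of 0.05 that chance alone gives. The fall of CIS1 was 29.2 fold (−4.87 ± 0.39, adjusted p = 1.18e-07) to 1.83 ± 0.835 CPM. PDR5 fell 11.1 fold to 217 ± 26 CPM (−3.47 ± 0.15, adjusted p = 1.68e-12), and PDR15 fell to 112 ± 40.1 CPM (−2.98 ± 0.19, adjusted p = 2.38e-09). YGR035C (−3.60 ± 0.50) and YDR406W-A (−2.99 ± 0.42), which the annotation lacks, fell by similar amounts, YGR035C by 2.86 without PSD1 replicate 2. For CIS1, PDR5 and PDR15, 6 of 6 deletion libraries lay below every PSD1 library. PDR3 itself is among the 25. It kept 11 counts over the 6 deletion libraries, 1 to 3 in each, which is 0.0738% of its level in PSD1 cells (counting interval 0.0368% to 0.132%).

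The other 24 genes that fell all had higher levels with PSD1 than with the empty vector and with V5-PSD1, and 14 of them by at least 2 fold over the empty vector. The same PSD1 libraries stand in each of these comparisons, so part of this may come from them. The 24 genes include BDH2 (−1.60 ± 0.17), GRE2 (−1.45 ± 0.19), the aldehyde reductase gene ARI1 (−1.26 ± 0.19), LAF1 (−1.24 ± 0.19) and RSB1 (−1.07 ± 0.14), whose product exports long-chain bases. Of the PDR regulon 12 of 19 fell and none rose (14 over the list alone), among them also SNQ2 (−0.83 ± 0.13). This list kept its camera call with the preset (adjusted p = 2.34e-41) and the estimated correlation (adjusted p = 0.000762). GRE2 was the 1 of 22 oxidative stress genes that fell. POL12 (YBL035C), a DNA polymerase alpha subunit gene, was the gene that rose, from 50.6 ± 2.64 to 60.4 ± 3.61 CPM (0.25 ± 0.05, adjusted p = 0.0276), in 6 of 6 libraries above every PSD1 library. It lost its call in 4 of 13 alternatives and without replicate 1, 2, 4 or 6 of PSD1 or 1, 3, 5 or 6 of the deletion (highest adjusted p = 0.101). MSP1 (−0.10 ± 0.06, adjusted p = 0.935), PDR1 (0.02 ± 0.07, adjusted p = 0.983) and PSD1 (0.25 ± 0.25, adjusted p = 0.942) did not pass.

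No gene passed in the other 24 lists, and over the lists alone 1 general stress gene was lower. Among their 661 genes, edgeR's quasi-likelihood test gave 15 with unadjusted p below 0.05, DESeq2 called 1 and limma on FPKM 0. HSP26 was at 1131 ± 715 CPM (−0.13 ± 0.37, adjusted p = 0.978). Camera passed for the proteasome (lower, adjusted p = 2.15e-05; adjusted p = 0.529 with an estimated correlation), mitochondrial ribosomal proteins (lower, adjusted p = 0.000357; adjusted p = 0.82 with an estimated correlation) and glycolysis (lower, adjusted p = 0.000828; adjusted p = 0.451 with an estimated correlation). It also passed for ribosome biogenesis (higher, adjusted p = 0.00418; adjusted p = 0.82 with an estimated correlation), general stress (lower, adjusted p = 0.0238; adjusted p = 0.823 with an estimated correlation) and oxidative stress (lower, adjusted p = 0.0238; adjusted p = 0.532 with an estimated correlation). Calls were lost for mitochondrial ribosomal proteins without PSD1 replicate 1 (adjusted p = 0.26) and for ribosome biogenesis without PSD1 replicate 1 or 5 or deletion replicate 2 (highest adjusted p = 0.272). They were lost for general stress without PSD1 replicate 3, 4, 5 or 6 or deletion replicate 2 (highest adjusted p = 0.944), and for oxidative stress without PSD1 replicate 3 or 6 or deletion replicate 2 or 6 (highest adjusted p = 0.274). Of the 291 genes at least 2 fold higher with PSD1 than with the empty vector, 15 fell in the deletion, PDR3 among them, against 1.16 for independent lists. Because the PSD1 libraries stand in both comparisons, they were split by odd and even replicate numbers, which gave 13 of 267 and 10 of 319. Series 5 alone called 4 genes, series 6 alone 21 and DESeq2 42. No group carried the empty vector in the deletion strain, so an effect of the deletion without PSD1 overexpression was not measured.

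In the deletion against the empty vector, 1640 genes were higher and 1344 lower, 197 and 22 by at least 2 fold. The 22 became 35 without deletion replicate 3, 8 with series 5 alone and 13 with the loci of the reference annotation alone. HSP26 (3.77 ± 0.45, adjusted p = 1.97e-06), SSA3 (3.53 ± 0.35), HSP33 (2.89 ± 0.25), TMA10 (2.65 ± 0.13), RGI2 (2.56 ± 0.43), RGI1 (2.49 ± 0.22), HSP30 (2.48 ± 0.41) and SSA4 (2.41 ± 0.26) were among the highest. So were the Ty loci YPR137C-B (7.19 ± 2.05) and YNL054W-A (3.24 ± 1.22, or 3.99 without replicate 4 of the empty vector). YPR137C-B had counts in 5 of 6 deletion libraries. Without replicate 5 of the empty vector it was at least 185 fold higher against a floor of 3 counts over the group. That replicate was the only empty-vector library with counts, so this is no bound for the whole group. YNL054W-A lost its call without replicate 1, 2 or 3 of the empty vector or 1, 4 or 6 of the deletion (highest adjusted p = 0.0754). SLM6 (−2.87 ± 0.99), YML090W (−1.42), OPT2 (−1.18 ± 0.17), ARG3 (−1.05 ± 0.11), RPM2 (−1.03 ± 0.13), PTR2 (−1.02), SPS4 (13.2 ± 2.41 against 25.9 ± 4.17 CPM), FAR1 (327 ± 29.0 against 651 ± 63.2 CPM), ARG56 (−0.97) and MIS1 (−0.97 ± 0.08) were the lowest. SLM6 lost its call without replicate 3 of the empty vector (adjusted p = 0.0558) and was at −3.52 without deletion replicate 3. PSD1 was 42.2 fold higher (5.40 ± 0.32, adjusted p = 3.65e-10), MSP1 was higher by 0.23 ± 0.07 (adjusted p = 0.00602), and PDR1 did not pass (0.14 ± 0.07, adjusted p = 0.123). PDR3 had 0.164% of its empty-vector level (counting interval 0.0818% to 0.294%). In the PDR regulon 5 of 19 were higher, among them CIS1 (1.68 ± 0.50, adjusted p = 0.00951) and HXT9 (1.18 ± 0.26), and 2 were lower, PDR5 (−0.42, adjusted p = 0.0213) and IPT1 (−0.21, adjusted p = 0.0114; chosen after its values were seen), with camera adjusted p = 0.389. CIS1 lay above every empty-vector library in 6 of 6 deletion libraries, and with series 5 alone it did not pass (1.53, adjusted p = 0.213).

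The deletion strain shared many changes with PDR3 cells. Of the genes called against the empty vector, 1548 were higher and 1287 lower in both strains, and 3 were opposite. Independent lists would share 487 and 362. The same empty-vector libraries stand in both comparisons. With the libraries split between the comparisons, 980 and 1135 genes were higher and 747 and 906 lower in both. The log2 fold changes correlated across genes with r = 0.877, against at most 0.644 in simulated unchanged groups and 0.760 and 0.777 in these splits. The covariance was 0.290, against a simulated 0.0318. Genes are not independent replicates. The simulation drew each gene independently, so its values can spread less than those of real unchanged groups.

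In the deletion against the empty vector, 24 of 25 heat shock genes were higher (camera adjusted p = 4.31e-17; adjusted p = 0.177 with an estimated correlation), as were 32 of 33 proteasome genes (camera adjusted p = 4.53e-13; adjusted p = 0.392 with an estimated correlation). Mitochondrial ribosomal proteins had 62 of 67 higher (64 over the list alone), such as RSM19 at 0.84 ± 0.13, with camera adjusted p = 3.20e-17 (adjusted p = 0.444 with an estimated correlation). Mitochondrial chaperones had 12 of 19 higher and 1 lower (13 and 1 over the list alone), with HSP10 at 1.52 ± 0.12 (camera adjusted p = 2.44e-05; adjusted p = 0.23 with an estimated correlation). Cytosolic ribosomal proteins had 128 of 138 lower and 1 higher (129 and 1 over the list alone; camera adjusted p = 3.85e-29; adjusted p = 0.407 with an estimated correlation). Oxidative phosphorylation had 31 of 36 lower (33 over the list alone), as ATP2 (−0.69 ± 0.13) was, with camera adjusted p = 1.59e-12 (adjusted p = 0.392 with an estimated correlation). In the iron regulon 7 of 21 were higher, with FIT3 at 1.05 ± 0.26 and FIT2 at 74.1 ± 124 CPM (2.03 ± 0.57), both cell wall proteins of siderophore uptake (camera adjusted p = 0.174). FIT2 ran from 19.3 to 327 CPM in the deletion, in 3 of 6 libraries above every empty-vector library, and was at 0.68 without deletion replicate 3. Of 46 ribosome biogenesis genes 44 were lower, with RPA135 at −0.87 ± 0.12 (camera adjusted p = 3.89e-17; adjusted p = 0.392 with an estimated correlation). General stress had 26 of 30 higher, with HXK1 at 2.29 ± 0.11 (camera adjusted p = 2.80e-11; adjusted p = 0.392 with an estimated correlation), and oxidative stress 16 of 22 (17 over the list alone), with AHP1 at 2.14 ± 0.17 (camera adjusted p = 1.80e-05; adjusted p = 0.392 with an estimated correlation). Amino acid synthesis had 28 of 39 lower and 3 higher (28 and 4 over the list alone), with LEU9 at −0.87 ± 0.10 (camera adjusted p = 1.50e-07; adjusted p = 0.392 with an estimated correlation). Galactose genes were lower in 7 of 11 cases and higher in 2 (camera adjusted p = 0.0348), a call lost without deletion replicate 1 (adjusted p = 0.0578). Camera also passed for import (19 of 35 higher, 1 lower, adjusted p = 0.00139), glycolysis (8 of 16 higher, adjusted p = 0.00638) and ergosterol synthesis (11 of 24 higher, adjusted p = 0.0136). None of these calls held with an estimated correlation. For histones and mating type alpha no gene passed, while 2 of their 12 genes had unadjusted p below 0.05, DESeq2 called 2 and limma 1.

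With the V5-PSD1 plasmid, 159 genes rose and 31 fell against the empty vector, 25 and 5 by at least 2 fold. The first 2 counts were 316 and 67 without V5-PSD1 replicate 3, and 89 and 18, 106 and 19, and 98 and 19 without its replicates 1, 2 and 4. They were 95 and 19 without replicate 3 of the empty vector, and without its replicate 4 there were 128 genes, 26 of them lower. The 5 became 3 without replicate 2 or 3 of the empty vector or 1, 2 or 5 of V5-PSD1. BTN2 (YGR142W, chromosome VII, 772454 to 773686), which encodes a factor that sorts misfolded proteins, rose from 77.0 ± 16.7 to 407 ± 54.0 CPM (2.41 ± 0.21, adjusted p = 1.78e-07), in 5 of 5 libraries above every empty-vector library. The Hsp70 genes SSA4 (1.99 ± 0.26) and SSA1 (YAL005C; 1.56 ± 0.11, from 1990 ± 223 to 5861 ± 264 CPM, adjusted p = 3.02e-08) rose with it. Of 25 heat shock genes 21 rose and none fell (24 over the list alone), and camera passed with the preset (adjusted p = 6.32e-45) and the estimated correlation (adjusted p = 0.00761). HSP26 rose by 1.55 ± 0.42 with adjusted p = 0.0471, in 4 of 5 libraries above every empty-vector library, and lost its call in 7 of 13 alternatives and in 15 of 22 runs without 1 library (highest adjusted p = 0.144, without V5-PSD1 replicate 1). With series 5 alone it was at 1.03 (adjusted p = 0.735) and with series 6 alone at 2.75 (adjusted p = 0.00907). SUC2 (1.45 ± 0.19), HXK1 (1.43 ± 0.11), RGI1 (1.42 ± 0.22), TMA10 (1.41 ± 0.13) and HXT7 (1.40 ± 0.26) also rose, and so did YFR052C-A (1.59 ± 0.20), which the annotation lacks. PSD1 rose 57.3 fold (5.84 ± 0.33, adjusted p = 7.23e-10).

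Galactose genes fell with the V5-PSD1 plasmid. GAL7 (YBR018C) went from 5275 ± 243 to 2495 ± 422 CPM (−1.08 ± 0.13, adjusted p = 1.33e-05) and GAL1 (YBR020W) from 11438 ± 482 to 6293 ± 641 CPM (−0.86 ± 0.10, adjusted p = 1.53e-05), and 8 of 11 genes of the list fell (10 over the list alone), GAL10 (−0.78 ± 0.10), GAL2 (−0.75 ± 0.12) and GAL80 (−0.71 ± 0.11) among them. Camera passed with the preset (adjusted p = 1.37e-16) and the estimated correlation (adjusted p = 0.0319). YFL067W (−1.23 ± 0.31), SDD1 (−1.17 ± 0.13), OPT2 (−1.06 ± 0.18), RGL1 (−0.97 ± 0.13) and FAR1 (−0.88 ± 0.10), which encodes an inhibitor of the cell cycle kinase, fell as well. YFL067W lost its call without replicate 1, 2 or 3 of the empty vector or 1, 2 or 5 of V5-PSD1 (highest adjusted p = 0.112).

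In the PDR regulon none of 19 genes passed with V5-PSD1. edgeR's quasi-likelihood test gave 1 with unadjusted p below 0.05, and DESeq2 and limma called 0 (camera adjusted p = 0.575). CIS1 was at 0.885 ± 0.421 CPM (0.57 ± 0.56, adjusted p = 0.621), PDR3 at 81.8 ± 9.49 CPM (−0.05 ± 0.11), MSP1 at −0.01 ± 0.07 (adjusted p = 0.967) and PDR1 at −0.02 ± 0.07 (adjusted p = 0.938), and none of the 4 passed. On simulated counts 82.1% of 2-fold changes were recovered in this comparison. This share covers genes of all levels, each simulated at its mean over all 22 libraries, so it says little about CIS1 at its level here. A p above the threshold does not show that CIS1 stayed level.

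Other stress lists moved with V5-PSD1 as well. Mitochondrial chaperones rose in 7 of 19 cases, with HSP78 at 0.94 ± 0.12 and HSP60 at 0.83 ± 0.11 (camera adjusted p = 3.41e-06; adjusted p = 0.177 with an estimated correlation). General stress genes rose in 6 of 30 cases (8 over the list alone), among them HSP12 (1.08 ± 0.26; camera adjusted p = 2.93e-10; adjusted p = 0.407 with an estimated correlation). Of 33 proteasome genes 6 rose, RPN4 (0.61 ± 0.11) the most, and 25 over the list alone (camera adjusted p = 4.12e-14; adjusted p = 0.392 with an estimated correlation), while DESeq2 called 11 and limma 1. Of 67 mitochondrial ribosomal protein genes 1 rose, RSM28 (0.24 ± 0.06), and 11 over the list alone (camera adjusted p = 2.70e-13; adjusted p = 0.455 with an estimated correlation), while DESeq2 called 5 and limma 0. Of 35 import genes 1 rose, SAM37 (0.24 ± 0.06; camera adjusted p = 0.000152; adjusted p = 0.455 with an estimated correlation). Camera passed for oxidative stress with 2 of 22 higher, AHP1 (0.91 ± 0.17) and TRX2 (camera adjusted p = 0.003; adjusted p = 0.455 with an estimated correlation), and for glycolysis with 3 of 16 higher, PGK1 (0.60 ± 0.12) among them (camera adjusted p = 0.016; adjusted p = 0.532 with an estimated correlation). Phospholipid synthesis had 2 of 16 lower (3 lower and 1 higher over the list alone), EPT1 (−0.44 ± 0.10) and EKI1 (−0.33 ± 0.08; camera adjusted p = 0.000813; adjusted p = 0.453 with an estimated correlation). Ribosome biogenesis stood lower in camera (adjusted p = 3.69e-08; adjusted p = 0.499 with an estimated correlation) while no member passed. In that list 4 of 46 had unadjusted p below 0.05, and DESeq2 and limma called 0.

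Several of these calls with V5-PSD1 were lost when single libraries were left out. SAM37 lost its call in 9 of 13 alternatives and in 16 of 22 runs without 1 library (highest adjusted p = 0.172, without V5-PSD1 replicate 1), and TRX2 in 5 of 13 and 8 of 22 (highest adjusted p = 0.133, without V5-PSD1 replicate 1). RSM28 lost it without replicate 2, 3 or 4 of the empty vector or 1 or 5 of V5-PSD1 (highest adjusted p = 0.0813), and HSP12 without replicate 3, 4 or 5 of the empty vector or 1 or 2 of V5-PSD1 (highest adjusted p = 0.112). Of the proteasome genes PRE3 lost it in 5 of 13 alternatives and without replicate 1, 2 or 3 of the empty vector, 4 of the deletion or 1, 2 or 4 of V5-PSD1 (highest adjusted p = 0.103). PUP2 lost it in 7 of 13 alternatives and 8 of 22 runs (highest adjusted p = 0.14, without V5-PSD1 replicate 1), and PRE4 in 4 of 13 and 0 of 22. EPT1 lost it without replicate 4 of the empty vector or 4 or 5 of V5-PSD1 (highest adjusted p = 0.0896), and EKI1 without replicate 1 or 4 of the empty vector or 1, 2 or 4 of V5-PSD1 (highest adjusted p = 0.0914). The camera call of glycolysis was lost without replicate 5 of the empty vector (adjusted p = 0.0922) or 3 of V5-PSD1 (adjusted p = 0.117).

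Amino acid synthesis genes rose in 4 of 39 cases, with ARG3 (0.63 ± 0.11) and ARG8 (0.55 ± 0.08; camera adjusted p = 0.171), and ergosterol genes in 2 of 24, with ERG28 at 0.49 ± 0.07 (camera adjusted p = 0.0633). Of the others that rose in these lists, CPA1 lost its call in 6 of 13 alternatives and in 15 of 22 runs without 1 library (highest adjusted p = 0.12). HOM2 lost it in 7 of 13 and 6 of 22, and ERG26 in 7 of 13 and 10 of 22 (highest adjusted p = 0.128). SUC2 and HXT7 were the 2 of 20 glucose-repressed genes that rose (camera adjusted p = 0.195). In the unfolded protein response ERV2 rose (0.37 ± 0.10), and in meiosis and sporulation REC104 (0.89 ± 0.19). ERV2 lost its call in 8 of 13 alternatives and in 12 of 22 runs without 1 library (highest adjusted p = 0.153, without V5-PSD1 replicate 1). No gene passed in 11 lists, which include oxidative phosphorylation and cytosolic ribosomal proteins. Among their 316 genes 10 had unadjusted p below 0.05, and DESeq2 and limma called 0. The count of 190 genes ran from 107 to 383 when single libraries were left out, series 5 alone called 14 and series 6 alone 176.

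**Figure D4:**
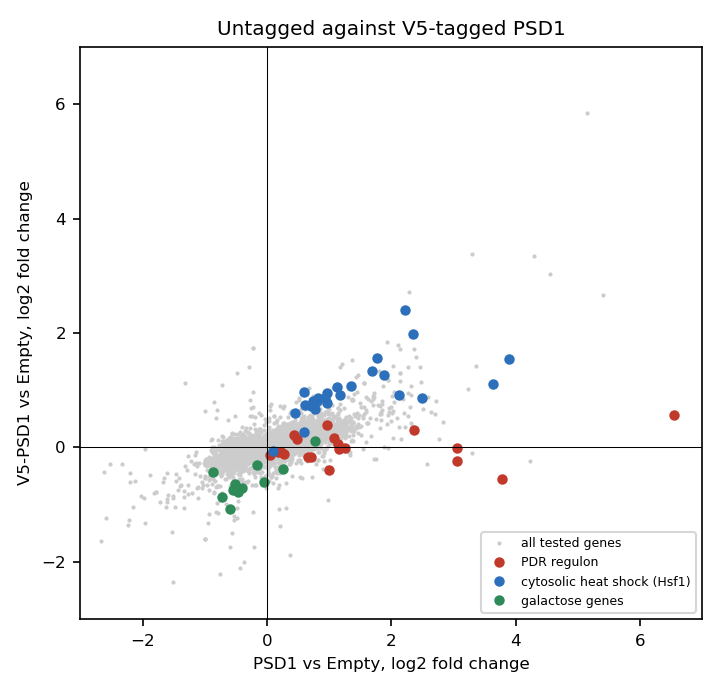
Log2 fold change of each gene in PSD1 against the empty vector (horizontal) and in V5-PSD1 against the empty vector (vertical), with 3 lists coloured; 9 genes lie outside the axes. CIS1 lies at 6.54 on the horizontal axis, and most galactose genes lie below 0 on the vertical axis.

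PSD1 against V5-PSD1 tests the difference between both plasmids directly, and 1277 genes were higher and 1264 lower with PSD1, 111 and 16 by at least 2 fold. The 16 became 25 without V5-PSD1 replicate 1, 10 without its replicate 5, 5 with series 5 alone and 9 with limma on FPKM. PSD1 mRNA itself was lower with the untagged plasmid (−0.69 ± 0.26, adjusted p = 0.0383), a call lost without replicate 1, 2 or 4 of PSD1 or 2, 3, 4 or 5 of V5-PSD1 (highest adjusted p = 0.0968). CIS1 was 63.0 fold higher with untagged PSD1 (5.98 ± 0.46, adjusted p = 2.71e-08), PDR5 9.83 fold (3.30 ± 0.16, adjusted p = 3.43e-11), PDR15 8.38 fold (3.07 ± 0.21, adjusted p = 4.33e-09) and PDR3 2.29 fold (188 ± 31.6 against 81.8 ± 9.49 CPM, adjusted p = 2.24e-07). MSP1 was higher by 0.34 ± 0.07 (adjusted p = 0.000376), and PDR1 did not pass (0.13 ± 0.07, adjusted p = 0.149). YGR035C (4.34 ± 0.56, or 3.54 without PSD1 replicate 2), GRE2 (2.61 ± 0.22), SSA3 (2.54 ± 0.33), the transaldolase gene NQM1 (2.38 ± 0.28), HSP26 (2.35 ± 0.42) and the loci YDR406W-A (3.39) and YOL150C (2.86), absent from the annotation, completed the largest rises. In the PDR regulon 16 of 19 were higher and none lower (camera adjusted p = 1.27e-10; adjusted p = 0.177 with an estimated correlation).

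Lower with PSD1 than with V5-PSD1 were the arginine genes ARG3 (144 ± 21.9 against 448 ± 21.4 CPM, −1.63 ± 0.11, adjusted p = 2.67e-09) and ARG8 (−1.07 ± 0.07), and the ribosomal protein gene RPL7B (−1.04 ± 0.08). ENA2 (−1.66 ± 0.36), RTC4 (−1.11 ± 0.22) and YML090W (−1.11) were lower too. ZPS1 (−2.45 ± 0.80), ADH4 (−1.82 ± 0.40), ZRT1 (−1.45 ± 0.54) and YOR387C (−1.69 ± 0.66) were lower as well, and all 4 lost their calls without the library series term. Without V5-PSD1 replicate 4 ZPS1 was at −1.91 (adjusted p = 0.0547), and YOR387C, which lost its call in 14 of 22 runs without 1 library, at −0.98 (adjusted p = 0.206). ZRT1 lost it without replicate 4, 5 or 6 of PSD1 or 4 or 5 of V5-PSD1 (highest adjusted p = 0.113), and YML090W without replicate 1, 2, 4 or 6 of PSD1 or 3 or 5 of V5-PSD1 (highest adjusted p = 0.125). Amino acid synthesis had 26 of 39 lower and 3 higher (28 and 5 over the list alone; camera adjusted p = 8.12e-09; adjusted p = 0.392 with an estimated correlation). Cytosolic ribosomal proteins had 129 of 138 lower and 1 higher (131 and 1 over the list alone; camera adjusted p = 1.15e-35; adjusted p = 0.392 with an estimated correlation). Oxidative phosphorylation had 29 of 36 lower (30 over the list alone), such as COX4 (−0.62 ± 0.09; camera adjusted p = 7.87e-12; adjusted p = 0.392 with an estimated correlation). Proteasome genes were higher in 30 of 33 cases (32 over the list alone; camera adjusted p = 7.61e-10; adjusted p = 0.41 with an estimated correlation), and mitochondrial ribosomal proteins in 54 of 67 (60 higher and 1 lower over the list alone; camera adjusted p = 4.77e-14; adjusted p = 0.455 with an estimated correlation). Of the heat shock genes 8 of 25 were higher and 1 lower (camera adjusted p = 0.0614). Galactose genes were higher with PSD1 in 6 of 11 cases and lower in 1, with GAL7 at 0.49 ± 0.12 (camera adjusted p = 0.0184; adjusted p = 0.522 with an estimated correlation; adjusted p = 0.0518 without V5-PSD1 replicate 1).

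Other lists differed between both plasmids as well. Ribosome biogenesis had 40 of 46 lower with PSD1 (42 over the list alone), with RPA135 at −0.78 ± 0.12 (camera adjusted p = 2.52e-15; adjusted p = 0.392 with an estimated correlation). General stress had 21 of 30 higher (23 over the list alone), with SPI1 at 2.02 ± 0.20 (camera adjusted p = 7.73e-09; adjusted p = 0.444 with an estimated correlation). Oxidative stress had 14 of 22 higher and 1 lower, with AHP1 at 1.40 ± 0.17 (camera adjusted p = 3.20e-05; adjusted p = 0.392 with an estimated correlation). Mitochondrial chaperones had 10 of 19 higher (12 higher and 1 lower over the list alone), with HSP10 at 0.70 ± 0.12 (camera adjusted p = 0.000637; adjusted p = 0.392 with an estimated correlation). Glycolysis had 10 of 16 higher and 1 lower, with ENO1 at 0.84 ± 0.24 (camera adjusted p = 0.00312; adjusted p = 0.455 with an estimated correlation), and the TCA cycle 9 of 15 lower, with FUM1 at −0.72 ± 0.16 (camera adjusted p = 0.00729; adjusted p = 0.657 with an estimated correlation). Import had 11 of 35 higher and 1 lower (8 and 1 over the list alone), with MIA40 at 0.70 ± 0.11 (camera adjusted p = 0.0368; adjusted p = 0.762 with an estimated correlation). The camera call of import was lost without PSD1 replicate 1 or 3 or V5-PSD1 replicate 3 or 4 (highest adjusted p = 0.101).

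The responses to both plasmids overlapped in part. In both, 149 genes rose and 27 fell against the empty vector, and 5 went opposite ways. With the empty-vector libraries split between the comparisons, 38 and 89 rose and 12 and 15 fell in both. Independent lists of the full sizes would share 47.2 and 8.34, which leaves out the shared libraries, so part of the overlap may come from them. The log2 fold changes correlated across genes with r = 0.665, and the same empty-vector libraries stand in both comparisons, which gave at most 0.622 in simulated unchanged groups. The correlation was lower without V5-PSD1 replicate 1 (0.558), 2 (0.592) or 4 (0.601) or replicate 3 of the empty vector (0.617). It was also lower with DESeq2 (0.511), without a filter (0.599) and with series 6 alone (0.580). Unchanged groups were simulated only for the main model with all libraries, so whether these values exceed their own no-change value is not known. The simulation drew each gene independently, so r and covariance can spread more widely in real unchanged groups. Whether 0.665 exceeds what shared libraries alone give is therefore not settled by 0.622. With the empty-vector libraries split between the comparisons r was 0.470 and 0.538, and the covariance 0.109 and 0.125. Without the split the covariance was 0.130, against a mean of 0.0300 and at most 0.0442 in simulated unchanged groups. Of the 291 genes at least 2 fold higher with PSD1 than with the empty vector, 243 (83.5%) were also higher with PSD1 than with V5-PSD1. Independent lists would share 59.2, and splits of the PSD1 libraries gave 205 of 267 and 225 of 319. Over all 5 comparisons camera passed in 61 of 130 tests of a list, and in 3 with an estimated correlation. Fry passed in 62 for direction and in 78 for change in either direction. In 9 tests the median, mean and test of a list differed in sign, and camera passed in 0 of them.

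Without the third replicates of PSD1 and of the PDR3 deletion, which lie apart from their groups, the counts were 3860 for PSD1 and 3080 for the deletion against the empty vector. They were 34 for the deletion against PSD1, 235 for V5-PSD1 and 2861 for PSD1 against V5-PSD1. This alternative was chosen after the data were seen.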

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

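In groups of 5 or 6 libraries, a library was marked where its gap to the nearest other library was large for the range of its group (Dixon's test at the 95% level). Of 81 such tests 8 were marked, and chance marks about 1 in 20 groups. CIS1 was at 120 CPM in the second PSD1 replicate, against 13.7 to 53.2 CPM in the other PSD1 libraries. Ribosomal RNA took 0.608% of the counts in the fourth PSD1 replicate, against 0.155% to 0.204% in the others. In the third replicate of the PDR3 deletion CIS1 was at 3.44 CPM (others 1.10 to 1.84), PDR15 at 190 CPM (75.7 to 113), HSP26 at 2540 CPM (505 to 1054) and SSA3 at 1820 CPM (454 to 915). SNQ2 was at 199 CPM in the second V5-PSD1 replicate (others 248 to 266), and GAL1 at 7430 CPM in the third (5874 to 6120).

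In 5 genes the plasmids with PSD1 and V5-PSD1 moved the level in opposite directions against the empty vector. The direct test of PSD1 against V5-PSD1 passed for each, which was also required for this list. In the same model that test is the difference of the 2 opposite changes, so its pass is no separate support. ARG3 fell with PSD1 and rose with V5-PSD1 (0.63), with a difference between both plasmids of −1.63 (adjusted p = 2.67e-09). ARG8 was at −0.52 and 0.55 (difference −1.07, adjusted p = 4.82e-09), HOM2 at −0.30 and 0.26 (difference −0.56, adjusted p = 2.25e-06) and YGR210C at −0.13 and 0.32 (difference −0.45, adjusted p = 1.54e-06). PCL10 went the other way, with 0.26 and −0.37 (difference 0.63, adjusted p = 1.99e-05). The direct test kept its call without any 1 library for all 5 genes, while some calls against the empty vector were lost. HOM2 lost that with V5-PSD1 in 7 of 13 alternatives and without replicate 1, 3 or 4 of the empty vector, 4 of the deletion or 1 or 4 of V5-PSD1 (highest adjusted p = 0.0961). PCL10 lost it with V5-PSD1 without replicate 3 of the empty vector or 1, 2 or 4 of V5-PSD1 (highest adjusted p = 0.0905) and with PSD1 without replicate 4 of the empty vector or 2 of PSD1 (highest adjusted p = 0.056). YGR210C lost it with PSD1 without replicate 1, 4 or 5 of the empty vector or 4 or 5 of PSD1 (highest adjusted p = 0.0828).

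Of the tests below, those of the sum over Ty loci and of promoter competition were written before their result was seen, and all others were chosen only after the result was seen.

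Ty elements were among the largest changes with the PSD1 plasmid: of 60 tested Ty loci 15 passed, 5 higher and 10 lower. Over all genes 3552 of 6278 passed, so Ty loci were not called more often than other genes. By at least 2 fold 7 Ty loci changed, against 333 of all genes. No biological explanation of the Ty changes was tested, since no group differs in Ty activity by design. Reads divided unevenly between near-identical copies could give this, but the sum over all Ty loci moved by −0.364 (permutation p = 0.193) with an SD within groups of 0.362 (PSD1) and 0.484 (empty vector), so this cannot tell, once that spread was weighed as well, which was decided after the result was seen. Strains that carry different Ty copies could give it too: 1 of the 15 loci, YBL005W-A next to PDR3, had counts in every library of a group and 0 in every library of the other, which cannot tell. Strains that differ beside PDR3 could add to the rise of PDR3 with PSD1 (1.14) and to the PDR calls against the empty vector and V5-PSD1, and the groups do not separate strain from plasmid. V5-PSD1 replicate 1, which also had 0 counts at that locus, had PDR3 at 74.1 CPM and PDR5 at 192 CPM, in 1 library.

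Galactose genes were lower with the V5-PSD1 plasmid, and 7 of 11 were also lower, with 2 higher, both with PSD1 and in the deletion. With V5-PSD1, a smaller share of reads left by the PSD1 transcript might lower these genes. The largest loss of that share, −0.0432 on the log2 scale, excludes this as the whole cause (GAL1 fell by 0.86). Weaker induction of whole cultures would tie low PSD1 to low galactose genes, and competition of plasmid promoters for the galactose activator would tie high PSD1 to low galactose genes. Over 17 libraries with a PSD1 plasmid the residuals correlated with r = 0.377 (permutation p = 0.192; after adjustment for 2 relations 0.280), with 0.484 in series 5 and −0.433 in series 6, so neither can be told from this test. Within groups r was 0.247 for PSD1 (n = 6), 0.340 for the deletion (n = 6) and 0.966 for V5-PSD1 (n = 5; exact permutation adjusted p = 0.025 over 3 groups, chosen after the values were seen). Libraries that differ in induction could give a positive r with or without competition. These values therefore decide neither and leave the difference between the plasmids open. Spearman's coefficient was 0.299 (permutation p = 0.280), and r was 0.404 without the 2 libraries farthest out.

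CIS1 stayed above the empty vector in the PDR3 deletion (exact permutation p = 0.00216 over 462 splits). Reads carried over from the PSD1 libraries could give this, but PDR3 was at 0.0756% of its PSD1 level where 2.32% would be needed, which excludes it. A single high library could give it as well, but without any 1 of the deletion libraries CIS1 stayed at 1.44 or more (highest adjusted p = 0.033), which excludes it. A route to CIS1 without Pdr3 is possible and was not tested, because no group carried the empty vector in the deletion strain.

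The libraries were also regrouped at random into groups of the same sizes, with 2 groups in each model. For PSD1 against the empty vector 1 of 100 splits, the real one, reached 3231 genes, and the highest other split had 2850. For V5-PSD1 it was 1 of 100 (109, highest other 22), for PSD1 against V5-PSD1 1 of 100 (2250, highest other 1189) and for the deletion against the empty vector 1 of 100 (3025, highest other 1674). In these 4 comparisons the real split had the most genes of the 100 drawn. The splits treat libraries as independent, which the labels do not say, so chance differences between cultures are not excluded. For the deletion against PSD1 2 of 99 splits had at least the 12 genes of the real one, and the other had 362. A split with many more genes than the real one points to a structure of the samples that is not the group, and which libraries carry it was not tested.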

How the results depend on the processing

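Of the gene results recomputed under alternatives other than leaving out a library, 5680 were the same, 362 weaker, 10 stronger and 1 reversed. The same means that a result kept its side of the threshold and, if it passed, its direction. A change of direction in a result that passed in neither run was counted as the same, also for lists. Of the list results 1704 were the same, 77 weaker, 36 stronger and 3 reversed, and of the counts 140 were within 1.5 fold and 16 moved. In the groups without its rise CIS1 rests on few counts. Over genes of all levels 68.7% to 76.1% of simulated 1.5-fold changes were recovered, and how this depends on depth was not tested. The alternatives without replicate 3 of PSD1 and of the deletion and with loci of the reference annotation alone were added after the data were seen. The latter gave 3427 genes for PSD1 and 2951 for the deletion against the empty vector, 26 for the deletion against PSD1, 149 for V5-PSD1 and 2531 for PSD1 against V5-PSD1. Without replicate 3 of PSD1 and of the deletion 19 genes at least 2 fold higher with PSD1 were lower in the deletion.

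The labels do not say that replicate numbers mark pairs. Residuals of libraries with the same number correlated at 0.088 to 0.609 between PSD1 and the deletion, where 4 of 6 libraries correlated best with their own number. They correlated at −0.056 to 0.21 between PSD1 and the empty vector (2 of 5 best with their own), at 0.104 to 0.241 between the deletion and V5-PSD1 (2 of 5), at −0.026 to 0.590 between the empty vector and V5-PSD1 (3 of 5), at −0.073 to 0.480 between PSD1 and V5-PSD1 (3 of 5) and at −0.128 to 0.237 between the empty vector and the deletion (2 of 5). By library set the ranges were 0.052 to 0.323 between the empty vector and PSD1, 0.063 to 0.418 between the empty vector and the deletion, −0.235 to 0.278 between PSD1 and V5-PSD1 and −0.106 to 0.258 between the deletion and V5-PSD1, and the other ranges were as by replicate number. With the replicate number as a block in place of the series, V5-PSD1 against the empty vector gave 293 genes, and with the library set as a block 424, where the number of PSD1 replicate 6 is no neighbour of its set. For the deletion against PSD1 these gave 23 and 33.

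With DESeq2 the deletion against PSD1 gave 42 genes (7 higher, 35 lower), and the correlation between the responses to both plasmids was 0.511. With series 5 alone (12 libraries) the counts were 2041 for PSD1 against the empty vector, 4 for the deletion against PSD1 (4 by at least 2 fold), 14 for V5-PSD1 (6 by 2 fold), 600 for PSD1 against V5-PSD1 (77 by 2 fold) and 760 for the deletion against the empty vector (113 by 2 fold). There, of the genes at least 2 fold higher with PSD1, 3 were lower in the deletion and 111 were higher than with V5-PSD1, and YOR387C was reversed at 0.061. With series 6 alone (10 libraries) the counts were 2946, 21, 176 (42 by 2 fold), 1983 and 2687 in the same order. There camera's direction turned for mitochondrial ribosomal proteins in the deletion against PSD1 (median −0.00576, −0.0572 with all libraries) and for the phosphate regulon with V5-PSD1 (0.151, 0.0119 with all), while their medians kept their sign, and the median of cytosolic ribosomal proteins with V5-PSD1 was reversed at −0.156. With V5-PSD1 both lists, which did not pass with all libraries, passed there in camera, cytosolic ribosomal proteins as lower (adjusted p = 7.42e-11) and the phosphate regulon as higher (adjusted p = 0.000405). With 2 groups alone the deletion against PSD1 gave 12 genes and V5-PSD1 109. On FPKM limma called 88 higher and 49 lower with V5-PSD1 (64.2% higher, against 83.7% in edgeR) and 1467 and 964 for PSD1 against V5-PSD1. The cause of these differences was not tested.

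With each library left out in turn, PSD1 against the empty vector gave 3307 to 3688 genes (308 to 398 by 2 fold), PSD1 against V5-PSD1 2144 to 2696, the deletion against the empty vector 2703 to 3106 and the deletion against PSD1 19 to 29. V5-PSD1 against the empty vector gave 107 (without its replicate 1) to 383 (without its replicate 3). It moved by more than 1.5 fold without its replicates 2 (125) and 4 (117) and without replicate 3 of the empty vector (114) as well. The genes at least 2 fold higher with PSD1 that were lower in the deletion ran from 12 to 18, those higher than with V5-PSD1 from 222 to 264, and the correlation between both plasmids from 0.558 to 0.682. In the deletion against PSD1 the median of cytosolic ribosomal proteins ran from −0.0844 to 0.0403, and was reversed without PSD1 replicate 1 and without deletion replicate 3. In these runs camera passed for the list as higher (adjusted p = 0.0457 and 0.00279). With all libraries camera did not pass for it (adjusted p = 0.15). The median of ribosome biogenesis ran from −0.0124, reversed without deletion replicate 2, to 0.121. Of gene results in these runs 9948 were the same, 320 weaker and 6 stronger, of list results 2776 the same, 31 weaker, 50 stronger and 3 reversed, and of counts 259 within 1.5 fold and 5 moved.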

Other observations

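The genes here that fell with the PDR3 deletion were chosen after their values were seen. The ceramide synthase gene LAC1 fell by 0.69 (adjusted p = 0.00129), the fatty acid hydroxylase gene SCS7 by 0.70 (adjusted p = 0.00212) and IPT1, whose product adds the last head group to inositol sphingolipids, by 0.39 (adjusted p = 0.0013). PDR16 (−0.88), which transfers phosphatidylinositol, and ICT1 (−0.99), a lysophosphatidate acyltransferase gene, fell as well. ICY1 (−1.01), ATG40 (−0.68), MIG2 (−0.65), VHR1 (−0.55), PGA3 (−0.47), TVS1 (−0.42) and SFT2 (−0.37) were the others outside the drug resistance list, beside those the report names. Of the 24 genes that fell beside PDR3, 7 stayed above the empty vector in the deletion, among them GRE2 (1.31) and ATG40 (0.84).

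The zinc-regulated genes ZRT1, ZPS1 and ADH4 had different values of PSD1 against V5-PSD1 in the library series, and this grouping was made after their values were seen. ZRT1, a zinc transporter gene, was at −0.13 in series 5 and −3.09 in series 6, ZPS1 at −0.52 and −4.73 and ADH4 at −0.59 and −3.06. The test of group by series over all genes passed for 0 genes in this comparison. Of 6278 genes 55 had p below 0.05, under the share of 0.05 that chance alone gives. The 0 calls therefore do not show that the series were alike. The test passed for 3, 0, 0 and 1 genes in PSD1 against the empty vector, the deletion against PSD1, V5-PSD1 against the empty vector and the deletion against the empty vector.

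PSD1 took 0.0245% to 0.0601% of the counts with the empty vector, 0.814% to 2.38% with PSD1, 1.39% to 2.60% in the deletion and 1.79% to 2.97% with V5-PSD1. Ribosomal RNA took 0.0852% to 0.608% of the counts of a library. The summed Ty loci took 0.332% to 1.10% of the counts of a library, and single Ty loci had a median SD within groups of 0.676, against 0.155 for other genes of like level.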
